A study of Mus musculus with 27 samples.

How the data were processed

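The series holds 27 mouse samples, all C57BL/6 and from postnatal day 1 cortex per the labels. RNA was sequenced from 15 samples in 5 groups of 3: control microglia at day 2 and at day 7, ND1-transduced microglia at day 2 and at day 7, and cultured cortical neurons. CpG methylation was measured by bisulfite sequencing in 1 control microglia library and 1 ND1 library, whose labels give no day. Another 10 samples are chromatin immunoprecipitation libraries (histone marks, FLAG and input), which were not analysed here. Per the labels, ND1 was delivered by lentivirus with M2rtTA, a doxycycline-responsive activator, and transduced cells were moved to a neuronal medium with BDNF, GDNF and NT3 and given doxycycline 1 time. The labels do not spell out ND1 and do not state the medium of the control cells. They also do not say whether replicates are separate cultures, so every p-value here measures only the spread between these samples.

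The RNA tables hold gene-level FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) computed by the authors. Per the submitters' processing notes, RNA reads were handled with TopHat, Bowtie2, Cuffdiff and Cufflinks on the mm10 build, with no versions given. The same notes name Bowtie2 2.2.4, SAMtools 0.1.19 and MACS 1.4.1 for the immunoprecipitation libraries. The bisulfite tables hold a methylated fraction per CpG position, as deposited, with no read counts, so the depth behind each methylation value is unknown and no interval for counting error is given. The tools used for the bisulfite reads are not given in the sources used here. The RNA files hold no read counts either. Library depth was therefore described by the FPKM sum and by the worth of 1 read, read from the spacing of the lowest values and given relative to control day 2 replicate 1.

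Each RNA table lists 24293 gene symbols, of which 24148 matched the RefSeq gene table, 1108 of them through a synonym. Altered, date-like symbols numbered 27, and 4 entries carried a duplicated symbol and were kept out of the gene lists. Symbols at 0 in all 15 libraries numbered 4024, and no 2 libraries were identical. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 13602. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a group mean for each of the 5 groups, an intensity trend in the prior variance, no replicate block and 10 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 fold change of at least 1, and fold changes are given on this log2(FPKM + 1) scale, which understates changes of weakly expressed genes. The design, the lists and the thresholds were fixed before the data were examined.

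The comparisons numbered 8: ND1 against control at day 2 and at day 7, the difference of these effects (interaction), day 7 against day 2 within control and within ND1 cells, neurons against control microglia of each day, and ND1 day 7 against neurons. Overlaps of called genes were counted between comparisons that share no library. Neuron-high and neuron-low genes were also used to place each library on the log2 distance from the control day 2 mean to the neuron mean. Neuron-high genes for shares of ND1 day 7 had a neuron mean of at least 20 times that of control day 7, at least 10 FPKM in neurons and ND1 day 7, and no 0 in ND1 or neuron libraries. Control-high, neuron-low genes had at least 50 FPKM in control day 7, a neuron mean of at most 1% of it and no 0 in day 7 libraries. Small RNA genes were left out of both, and Neurod1 of the former. To check whether replicate numbers pair libraries, each gene's deviations from its group mean were correlated between libraries of equal number in different groups. Of 30 such pairs, 2 had an r over 0.1, with a range of -0.226 to 0.161.

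Gene lists numbered 28: pan-neuronal cytoskeleton and RNA-binding markers, neurogenic transcription factors, synaptic vesicle and presynaptic genes, postsynaptic and glutamate receptor genes, GABAergic and striatal genes, voltage-gated channels, homeostatic microglia markers, myeloid lineage transcription factors, pan-myeloid markers, cytokines and chemokines with NF-kappaB targets, interferon-stimulated genes, antigen presentation, phagocytosis and lysosome, cell cycle, Notch pathway, DNA methylation enzymes and readers, Polycomb and trithorax, cholesterol biosynthesis, glycolysis, astrocyte, oligodendrocyte, fibroblast and mural, endothelial and neural progenitor markers, heat shock and stress, p53 and apoptosis, immediate early genes, and mitochondrially encoded genes. The last has 13 members, of which 0 are listed in the RNA tables, so 27 lists were tested. Each was tested with limma's camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Members were counted with p adjusted over all tested genes and adjusted over the list alone. The counts were equal in every list and comparison.

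Genes named in the text follow a rule: Neurod1 in every library; for each comparison other than the interaction, up to 6 rises and 6 falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the replicates (chance gives no overlap for 10% of genes); up to 4 members of each list with the largest absolute change; Scrt1, Meis2, Pou3f2, Dnmt1, Dnmt3a, Tet1, Tet2, Tet3 and Rest; and the 5 largest falls and rises of methylation at gene ends. Some genes that the rule picks are not reported here. A member given without a verb of change did not pass. Other genes are named where stated as chosen after their values were seen. A symbol listed at 0 in libraries of a group is given as values per library without a fold, except for the interaction of Mir7035.

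Methylation was compared at positions listed in both libraries, in 1 kb windows with at least 3 shared positions, and at RefSeq genes (GRCm38, 21631 protein-coding genes). Means are unweighted over positions. The annotation used gives no strand, so the promoter was replaced by the CpG-richer gene end, defined as the annotated end with more listed positions, from 1000 bp outside to 500 bp inside. The body of a gene was its whole annotated span, which includes the inner part of both ends. Means pooled over positions were also taken for both ends of all genes, for bodies without the ends and outside protein-coding genes. Gene ends and bodies needed at least 5 shared positions. With 1 library per condition there is no replicate error and no test. Differences of at least 25 percentage points were counted, and the median difference of each gene set was placed among 10000 random sets of the same size matched on expression. Read minimums, read-weighted levels and Fisher tests on summed calls had been planned and were not run, because the tables give fractions alone.

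Alternatives covered the pseudocount (0.5 and 0.1), the filter on low values (none, or 5 FPKM), quantile normalization, median-ratio scaling, a replicate block, robust variance moderation, fits to the compared libraries alone, no fold threshold, and each library left out in turn, and, for methylation, window size, difference and gene-end size. Chosen after the data were seen were the omission of genes listed at 0 in any library, the omission of small RNA genes, the removal of an ND1 day 7 share from ND1 day 2 libraries or of a control day 7 share from ND1 day 7 libraries, and a minimum of 10 positions per window. The fit was tested on simulated data built from control day 7 means and the residual spread of the fit, with shifts added under the ND1 day 7 label. Of genes shifted by log2 1.2, 65 of 67 were called (97.0%), at log2 2 all 67 and at log2 3 all 66, with 0 false calls. Only genes with a mean log2(FPKM + 1) over 3 were shifted, and far fewer than were called in the real data. Recovery of weaker genes was not tested. In simulated methylation data of 28892 windows, 200 of 200 windows of at least 5 positions lowered by 50 points were called, with 0 false calls. Positions there were given noise with an SD of 5 points, while real differences between the libraries had an SD of 10.9 points. The false-call rate of the real windows, above all those with few positions, is therefore not known from this. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for methylation, tables and figures.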

Results

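RNA was measured in 15 libraries, 3 each of control microglia at day 2 and day 7, ND1-transduced microglia at day 2 and day 7, and cultured cortical neurons. CpG methylation was measured in 1 control and 1 ND1 library. FPKM sums per library ranged from 429013 to 739846, and 10709 to 12092 genes per library reached 1 FPKM. The worth of 1 read relative to control day 2 replicate 1, where a lower value stands for a deeper library, lay between 0.732 and 1.13. Replicates of a group correlated at 0.975 to 0.986 across the 13602 tested genes. ND1 day 7 libraries correlated with neuron libraries at 0.898 to 0.909 and with control day 7 libraries at 0.579 to 0.608, while control day 7 and neuron libraries reached 0.427 to 0.447. Genes are not independent replicates, so these correlations across genes carry no p-value. The first principal component held 82.2% of the variance and the next 6.63%.

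Neurod1, a basic helix-loop-helix transcription factor of neuronal differentiation (mm10 chromosome 2, 79452637 to 79456636), was listed at 3073, 3454 and 3337 FPKM in the ND1 day 2 libraries. The control day 2 libraries gave 1.04, 1.15 and 1.08 FPKM. At day 7, the ND1 libraries gave 36.7, 32.6 and 32.5 FPKM and the control libraries 1.33, 1.19 and 2.16. Neurons gave 6.43, 6.79 and 6.38 FPKM. Neurod1 thus rose by log2 10.62 (SE 0.10, limma adjusted p = 2.22e-16) at day 2 and by 3.79 (SE 0.10, limma adjusted p = 9.62e-14) at day 7. Within ND1 cells it fell by 6.56 (SE 0.10) between the days. The tables do not separate transcripts of the delivered construct from those of the endogenous gene.

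**Figure D1:**
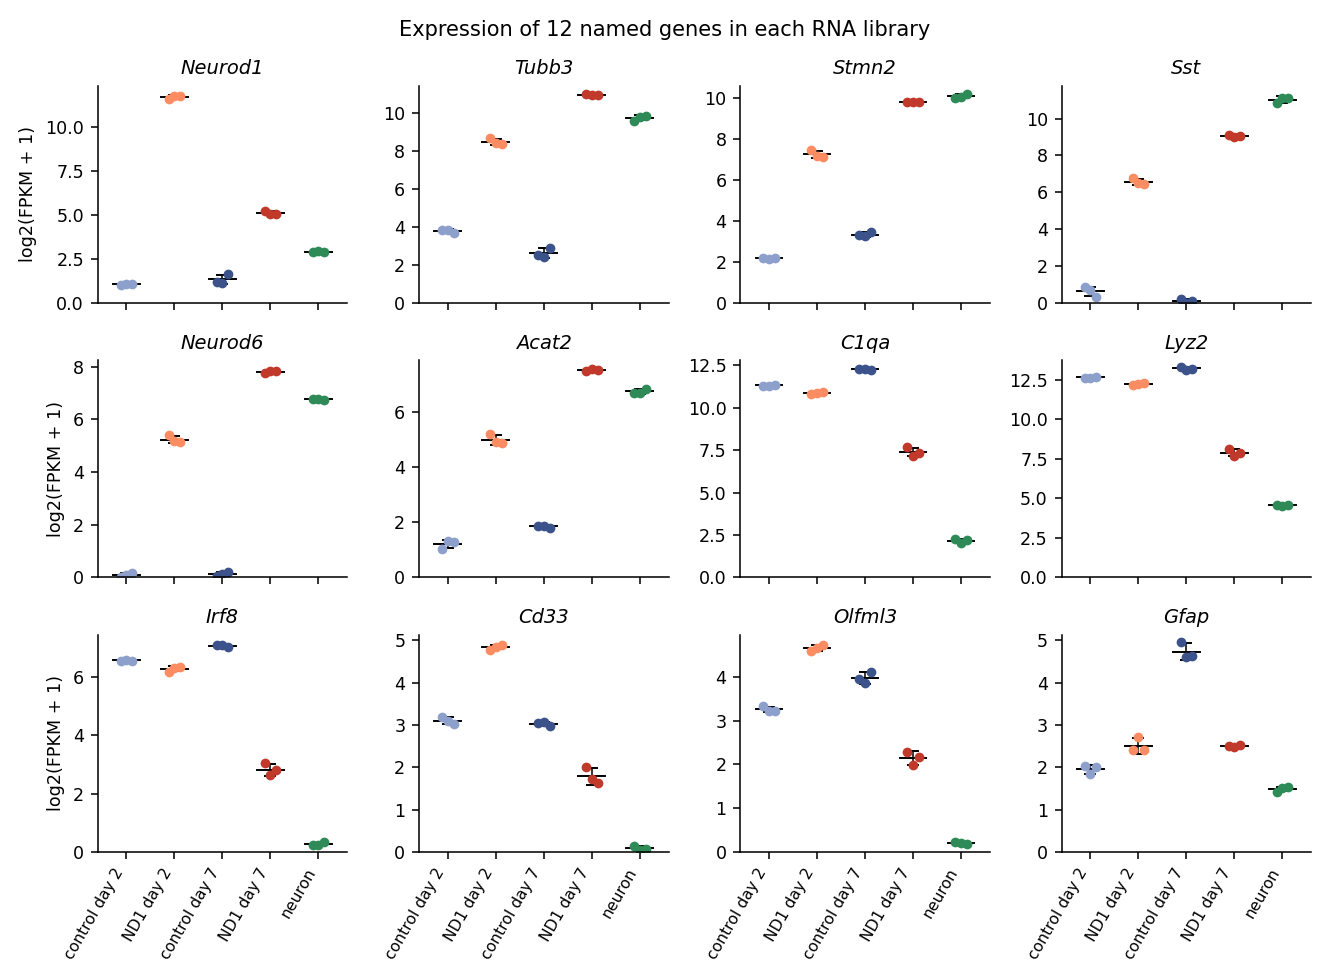
Expression of 12 named genes, as log2(FPKM + 1), in the 15 RNA libraries. Points are libraries, lines are group means and bars are the SD of the log2 values (n = 3). Neurod1 lies near 3288 FPKM in ND1 day 2 libraries, and C1qa falls from 4904 FPKM in control to 169 FPKM in ND1 libraries at day 7.

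The day 2 comparison addressed the early response to ND1 transduction, which came with lentivirus, doxycycline and a neuronal medium. Since the medium of the control cells is not stated, an ND1 effect, here and below, cannot be told apart from an effect of these treatments. Genes of the neuronal cytoskeleton rose from near background: Gap43, a growth cone protein, went from 1.92 ± 0.150 FPKM in control libraries to 129 ± 16.0 FPKM in ND1 libraries (SD, n = 3 each; log2 change 5.47, SE 0.12, limma adjusted p = 4.26e-13), and Stmn2, a microtubule regulator of growing axons, from 3.54 ± 0.0650 to 150 ± 18.8 FPKM. The neuronal transcription factor gene Neurod6 went from 0.0664 to 36.6 ± 3.75 FPKM (log2 change 5.13, SE 0.06, limma adjusted p = 1.64e-15), and Sst, which encodes the neuropeptide somatostatin, from 0.569 ± 0.273 to 94.3 ± 11.4 FPKM. Of 25 measured pan-neuronal markers 24 rose, among them Tubb3 (log2 change 4.70) and Crmp1 (4.61), as did 15 of 25 neurogenic transcription factors (log2 changes Neurod2 3.99, Bcl11a 3.29 and Myt1l 3.01), 23 of 26 synaptic vesicle genes (Syt4 4.45, Cplx1 3.53 and Syt1 3.04) and 17 of 22 postsynaptic genes (Camk2b 3.44 and Dlg2 2.99). Scrt1, Meis2 and Pou3f2, transcription factor genes, rose by log2 1.5 (SE 0.07), 1.31 (SE 0.10) and 1.62 (SE 0.07). Of the GABAergic and striatal list 6 of 24 rose, and of the voltage-gated channels 6 of 19 (Scn3b 1.90). Cholesterol synthesis genes also rose, in 11 of 20 cases. Acat2, an acetyl-CoA acetyltransferase, went from 1.32 ± 0.240 to 31.0 ± 4.10 FPKM, and Hmgcs1, which makes HMG-CoA, from 14.1 to 89.5 ± 8.11 FPKM. Removal of the ND1 day 7 share from ND1 day 2 libraries, chosen after the data were seen, left little of these changes. Pan-neuronal markers and synaptic vesicle genes had camera adjusted p = 0.00497 each, in place of 2.09e-17 and 5.75e-15, a remainder around a share that most of their members helped to set. Homeostatic markers were then called as higher (7.37e-05, against 0.638 before), and 3 of 27 lists were called in all. The cholesterol list turned (camera adjusted p = 0.592), and Acat2 (-1.04), Hmgcs1 (-0.93), Stmn2 (-0.78), Meis2, Syt1, Syt4, Scn3b, Dlg2, Pou3f2 and Neurod6 then had changes below 0. Gap43 (0.17), Tubb3 (0.67) and Crmp1 (0.28) no longer passed, while Sst (1.58) and Neurod2 (1.18) did.

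These 7 groups had camera adjusted p between 2.09e-17 and 7.65e-07, and with an estimated correlation adjusted p between 0.134 and 0.324. Beside them, the rise of 664 neuron-high genes over control day 2 stood at a near-constant fraction of their rise at ND1 day 7, with a median of 17.1% (interquartile range 16.3 to 17.6%). From the 5th to the 95th percentile the fraction went from 15 to 18.9%. Among these genes the median was 17.2% for 24 pan-neuronal markers, 17.1% for 9 neurogenic transcription factors, 17.4% for 21 synaptic vesicle genes and 17.0% for 10 postsynaptic genes. For 14 cholesterol synthesis genes more than 2 times higher at ND1 day 7 than in control day 2 it was 15.2%, with a wider range of 4.10 to 28.1% between the same percentiles.

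Microglial genes moved less at day 2, and called genes went in both directions. Most moved down by less than the fold threshold: 306 control-high, neuron-low genes stood at a median of 72.5% of control day 2 (interquartile range 65.1 to 81.1%). Ccl4, a chemokine gene, fell from 384 ± 4.27 FPKM in control to 162 ± 3.82 FPKM in ND1 libraries (SD, n = 3 each; log2 change -1.24, SE 0.07, limma adjusted p = 3.84e-09), and Cxcl10, an interferon-induced chemokine gene, from 137 ± 7.06 to 54.9 ± 1.68 FPKM. The genes with the largest falls also held H2-Q6 (log2 change -2.18, SE 0.47), an MHC class I gene, Gpr65 (log2 change -1.52, SE 0.08), which encodes a proton-sensing receptor, Fabp4 (-1.51, SE 0.07), a fatty acid binding protein gene, Thbs1 (-1.39, SE 0.06), which encodes thrombospondin 1, and Ifitm6 (-1.42, SE 0.12). H2-Q6 had the largest SE of those named, and stood at 45.05 FPKM in control day 2 but 0.00997 FPKM in control day 7 libraries. How reads were assigned among related MHC genes was not examined, so its fall is uncertain. Of the cytokine list 7 of 22 fell and 1 rose, with camera adjusted p = 0.000117, and adjusted p = 0.310 with an estimated correlation. Other microglial genes rose: Slco2b1, an organic anion transporter gene, by log2 3.02 (SE 0.09), Cd33, a sialic acid binding lectin gene, from 7.61 ± 0.458 to 27.7 ± 1.04 FPKM, and Olfml3 from 8.61 ± 0.405 to 24.4 ± 1.38 FPKM. Of the homeostatic microglia markers 5 of 21 rose and 0 fell, with a median log2 change of -0.14 and a mean of 0.26 (camera adjusted p = 0.638). Rest, which encodes a repressor of neuronal genes, was at 8.21 FPKM in control and 6.54 in ND1 libraries.

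Other lists called lower at day 2 held few called members: interferon-stimulated genes with 1 of 22 (camera adjusted p = 2.57e-06), pan-myeloid markers with 0 lower and 1 higher of 23 (0.000591), myeloid transcription factors with 2 lower and 1 higher of 19 (0.00253), the latter Mef2c, which neurons also express, phagocytosis with 0 of 23 (0.00253), antigen presentation with 0 of 18 (0.00279) and cell cycle with 0 of 23 (0.0316). With an estimated correlation these had adjusted p between 0.324 and 0.512. Fibroblast and mural markers were called higher, with 3 of 12 (camera adjusted p = 0.00237, and adjusted p = 0.134 with an estimated correlation). Those 3 were Thy1, Col1a1 and Acta2, whose changes of 1.18, 1.17 and 1.16 became 0.64, 0.59 and 0.64 after quantile normalization and no longer passed. The largest called members of these and the other lists had an SE of 0.0473 to 0.178 and limma adjusted p up to 5.75e-05. In all, 1237 genes rose and 84 fell, 9.71% of those tested. The count of 1237 was 98 once the ND1 day 7 fraction was removed, 817 after quantile normalization and 2367 with a pseudocount of 0.1, and the count of 84 was 41, 159 and 157. The fall to 98 is largely built in, since the day 2 rise of neuron-high genes set that fraction. Quantile normalization also ended the list calls for pan-myeloid markers, antigen presentation and phagocytosis (camera adjusted p 0.257, 0.0739 and 0.944, the highest of the alternatives, whose ranges began at 3.71e-05, 0.000738 and 0.000274), and a 5 FPKM filter that for cell cycle (0.0598, the highest of a range from 0.00122).

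At day 7 the comparison of ND1 with control microglia asked how far expression differed by then. Neuronal genes were far higher: Tubb3, the neuronal beta-tubulin gene, stood at 5.17 ± 1.16 FPKM in control and 1988 ± 38.7 FPKM in ND1 libraries (SD, n = 3 each; log2 change 8.35, SE 0.12, limma adjusted p = 2.96e-16). Neurod6 stood at 0.10 and 222 ± 6.91 FPKM, Syt4, a synaptotagmin gene, at 0.360 and 160 ± 8.87 FPKM, and Sst at 0.157, 0 and 0.0762 FPKM in the control libraries and 536 ± 16.8 FPKM in ND1 libraries. Rises covered 24 of 25 pan-neuronal markers (log2 changes Crmp1 7.79, Mapt 7.46 and Dpysl5 7.26), 22 of 25 neurogenic transcription factors (Neurod2 6.37, Bcl11a 6.16 and Sox11 6.02), 26 of 26 synaptic vesicle genes (Syt1 5.67 and Cplx1 5.64), 22 of 22 postsynaptic genes (Dlg2 5.53, Camk2b 5.24 and Gria2 4.54), 20 of 24 GABAergic and striatal genes (Gabra2 5.25) and 17 of 19 voltage-gated channels (Cacna2d1 3.85). Scrt1, Meis2 and Pou3f2 rose by 3.96 (SE 0.07), 4.10 (SE 0.10) and 3.84 (SE 0.07). Cholesterol synthesis genes rose in 19 of 20 cases, with Acat2 at 183 ± 4.30 FPKM against 2.62 ± 0.124 and Hmgcs1 at 491 ± 14.8 against 13.3 FPKM. Camera adjusted p for these 7 lists lay between 1.29e-08 and 1.69e-05, and with an estimated correlation adjusted p between 0.237 and 0.279.

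Microglial genes were far lower in ND1 cells at day 7. C1qa, which encodes a complement C1q chain, stood at 4904 ± 58.1 FPKM in control and 169 ± 30.3 FPKM in ND1 libraries (SD, n = 3 each; log2 change -4.87, SE 0.10, limma adjusted p = 4.57e-15). Lyz2, the macrophage lysozyme gene, stood at 9569 ± 523 and 237 ± 36.5 FPKM, Irf8, a myeloid transcription factor gene, at 134 ± 3.96 and 6.13 ± 1.03 FPKM, and Apoe, the apolipoprotein E gene, at 23615 ± 678 and 788 ± 157 FPKM. Apart from microRNA genes with values of 0, the largest fall under the naming rule was that of Cd5l, a macrophage scavenger protein gene, from 183 ± 16.5 to 1.83 ± 0.458 FPKM. Falls covered 22 of 23 pan-myeloid markers (log2 changes Fcgr1 -4.91 and Aif1 -4.68), 16 of 21 homeostatic markers (C1qb -4.87, C1qc -4.73 and Fcrls -4.69, with 1 rise), 16 of 19 myeloid transcription factors (Spi1 -4.14, Irf5 -4.42 and Cebpa -3.91, with 1 rise, that of Mef2c, which neurons also express), 22 of 22 interferon-stimulated genes (Irf7 -4.62, Zbp1 -4.41 and Ifit3 -4.39), 16 of 22 cytokine genes (Ccl4 -4.86, Ccl3 -4.38 and Ccl5 -4.07, with 1 rise), 16 of 18 antigen presentation genes (H2-K1 -4.51 and Psmb9 -4.37) and 22 of 23 phagocytosis and lysosome genes (Lgals3 -4.21 and Ctss -4.20). Camera adjusted p for these 7 lists lay between 2.56e-08 and 0.000225, and with an estimated correlation adjusted p = 0.237. Beside these falls stands the share of 306 control-high, neuron-low genes, taken after the neuron mean was subtracted from both groups. In ND1 libraries they stood at a median of 4.83% of their control level (interquartile range 4.13 to 5.87%).

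The remaining lists moved less evenly at day 7. Cell cycle genes fell in 8 of 23 cases, with Ccnd1 at log2 -3.12, Cdkn1a at -2.80 and Cdk1 at -2.20 (camera adjusted p = 0.00105), and p53 and apoptosis genes fell in 11 of 17 cases and rose in 1, with Casp8, an initiator caspase gene, at -3.49 (camera adjusted p = 0.00183). Both had adjusted p = 0.237 with an estimated correlation. Not called were Notch genes (5 higher and 5 lower of 13, camera adjusted p = 0.743), DNA methylation genes (3 and 4 of 14, 0.497), Polycomb and trithorax genes (5 and 4 of 21, 0.902), glycolysis genes (5 and 4 of 20, 0.626), neural progenitor markers (6 and 3 of 14, 0.425) and immediate early genes (4 and 3 of 16, 0.696). Heat shock genes (2 higher and 8 lower of 17, 0.0949), astrocyte markers (0 and 5 of 12, 0.264), oligodendrocyte markers (1 and 3 of 5, 0.139), fibroblast markers (7 and 1 of 12, 0.112) and endothelial markers (0 and 2 of 4, 0.261) were not called either. Within these lists Tet1, which encodes a 5-methylcytosine oxidase, rose from 0.0796 to 3.33 ± 0.267 FPKM (log2 change 2.00, SE 0.08), and Ezh2, the histone H3K27 methyltransferase gene, from 3.74 ± 0.496 to 24.8 ± 0.616 FPKM. Mbd2, a methyl-CpG reader gene, fell from 75.5 to 8.73 FPKM, and Gadd45b from 49.5 to 3.31 FPKM. Rest fell by 1.59 (SE 0.11, limma adjusted p = 2.54e-09). Dnmt1, Dnmt3a, Tet2 and Tet3 had log2 changes of 0.56, -0.91, 0.18 and 0.44 and did not pass. Over all lists, the called members among the 4 largest changes had an SE of 0.0401 to 0.254 and limma adjusted p up to 5.69e-06. In all, 3497 genes rose and 3332 fell, 50.2% of those tested, and without the fold threshold the counts were 6330 and 6015.

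**Figure D2:**
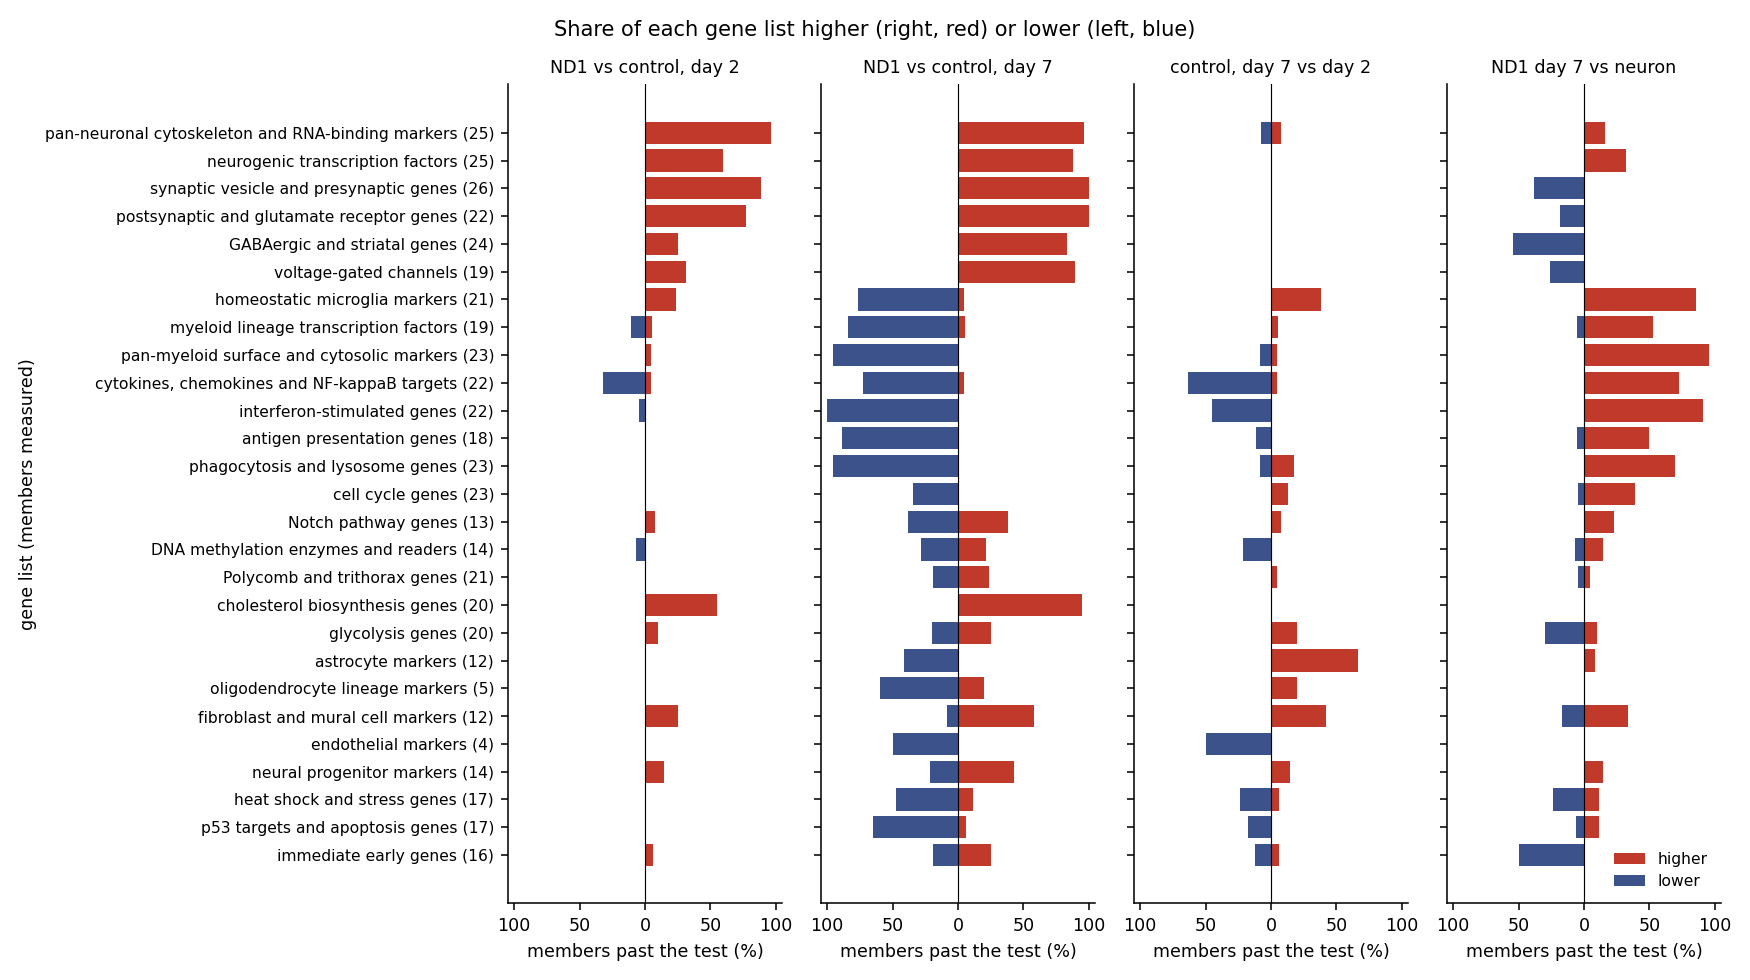
Share of measured members higher or lower (percent, horizontal axis) for each of the 27 measured gene lists in 4 comparisons. At ND1 day 7 against control, all 26 synaptic vesicle genes were higher and all 22 interferon-stimulated genes lower.

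The interaction asked which genes differed in their ND1 effect between day 7 and day 2. Neuronal genes had the larger effect at day 7: Dcx, a microtubule-associated protein gene of migrating neurons, by log2 3.72, Tubb3 by 3.65, the transcription factor gene Sox11 by 3.01 and Syt1 by 2.62. Dcx stood at 2.39 FPKM in control and 35.1 ± 3.03 in ND1 libraries at day 2, and at 0.529 and 214 ± 18.6 FPKM at day 7 (SD, n = 3 each). Myeloid genes had the lower effect at day 7, with differences of -4.92 for Lyz2, -4.42 for Apoe, -4.41 for C1qa, -4.25 for Irf7, which encodes an interferon regulatory factor, and -3.96 for Irf8. Of the lists, pan-neuronal markers (24 of 25), synaptic vesicle genes (25 of 26), neurogenic transcription factors (20 of 25), postsynaptic genes (19 of 22), GABAergic genes (19 of 24), channels (15 of 19) and cholesterol synthesis (18 of 20) had higher effects. Pan-myeloid (22 of 23), homeostatic (19 of 21), interferon-stimulated (22 of 22), phagocytosis (22 of 23), antigen presentation (16 of 18) and cytokine genes (14 of 22, with 2 higher) had lower effects, as did myeloid transcription factors (16 of 19, with 1 higher). Cell cycle (6 of 23), p53 and apoptosis (11 of 17, with 1 higher) and astrocyte genes (5 of 12) were also lower. These 17 lists had camera adjusted p between 1.41e-09 and 0.0291, and with an estimated correlation adjusted p between 0.20 and 0.295. The astrocyte call ended after quantile normalization (camera adjusted p = 0.0600, the highest of a range from 0.00424 over the alternatives). For the 4 largest called members of each list the SE was 0.0567 to 0.173. In all, 2790 genes had the higher and 2826 the lower effect at day 7.

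Control microglia were compared between the days to give the background of culture time. Inflammatory genes fell: Cxcl10 went from 137 ± 7.06 to 9.90 ± 2.38 FPKM (SD, n = 3 each; log2 change -3.69, SE 0.11), the interleukin gene Il1b from 50.4 ± 2.03 to 3.44 ± 0.260 FPKM, and Ccl5 from 11064 ± 323 to 1399 ± 67.1 FPKM. Of the cytokine list 14 of 22 fell and 1 rose (camera adjusted p = 2.29e-06, and adjusted p = 0.328 with an estimated correlation). The rise was Lcn2, the lipocalin gene, from 25.9 ± 3.06 to 262 ± 17.6 FPKM. Interferon-stimulated genes fell in 10 of 22 cases, with Rsad2 at log2 -2.32, Mx1 at -2.24 and Mx2 at -2.05 (camera adjusted p = 4.48e-08, and adjusted p = 0.412 with an estimated correlation). Homeostatic markers rose in 8 of 21 cases, with Cx3cr1, the fractalkine receptor gene, at log2 2.37 (SE 0.06) and Fcrls from 42.1 to 224 ± 10.0 FPKM (camera adjusted p = 0.000568, and adjusted p = 0.412 with an estimated correlation). Apoe rose from 2943 ± 16.9 to 23615 ± 678 FPKM, Cd5l from 3.87 ± 0.292 to 183 ± 16.5 FPKM and Serpina3n, a protease inhibitor gene, from 2.18 to 58.8 ± 6.09 FPKM. Dnmt3a, a de novo DNA methyltransferase gene, fell from 86.5 ± 1.25 to 28.5 ± 2.13 FPKM (log2 change -1.57, SE 0.06, limma adjusted p = 6.01e-11).

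Of the markers of other cell types, the astrocyte and fibroblast lists rose with time in control cells, while oligodendrocyte (1 of 5 higher, camera adjusted p = 0.216) and progenitor markers (2 of 14, 0.189) were not called. Astrocyte markers rose in 8 of 12 cases: Gfap, the astrocyte intermediate filament gene, went from 2.88 ± 0.282 to 25.7 ± 3.85 FPKM (SD, n = 3 each; log2 change 2.77, SE 0.10, limma adjusted p = 4.64e-11), and Aqp4, a water channel gene, from 0.564 to 8.44 ± 0.213 FPKM. The camera adjusted p was 6.02e-07, and with an estimated correlation adjusted p = 0.0158, the only list call of the 8 comparisons that held with it. Fibroblast and mural markers rose in 5 of 12 cases, with Acta2, the smooth muscle actin gene, from 0.721 ± 0.107 to 21 ± 1.17 FPKM and Tagln at log2 3.45 (camera adjusted p = 0.00786, and adjusted p = 0.283 with an estimated correlation). Cell cycle genes rose in 3 of 23 cases, with Ccnd1, Rrm2 and Birc5 (camera adjusted p = 0.000475), and glycolysis genes in 4 of 20, with Aldoc and Ldhb (0.0284). Heat shock genes fell in 4 of 17 cases and rose in 1 (0.0377), p53 genes fell in 3 of 17 (0.0284), antigen presentation genes in 2 of 18 (0.0284) and endothelial markers in 2 of 4 (0.0483). With an estimated correlation these 6 had adjusted p between 0.282 and 0.474. Across lists, the 4 largest called members each had an SE of 0.0343 to 0.178. In all, 531 genes rose and 516 fell, 7.70% of those tested, and 1115 and 777 with a pseudocount of 0.1. The endothelial call ended under 6 planned settings and without control day 7 replicate 3 (camera adjusted p = 0.0706, with a range of 0.0338 to 0.498 over the alternatives), and that of antigen presentation with a pseudocount of 0.1 (0.0512, the highest of a range from 0.0123).

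Within ND1 cells, the days were compared to follow the change in time. Inflammatory genes were among the largest falls: Ccl5 went from 7716 ± 268 to 82.7 ± 13.2 FPKM (SD, n = 3 each; log2 change -6.54, SE 0.09), Rsad2, an antiviral enzyme gene, from 850 to 13.2 FPKM (-5.91, SE 0.07) and Irf7 from 1590 to 29.3 ± 4.04 FPKM. Interferon-stimulated genes fell in 22 of 22 cases, phagocytosis genes in 23 of 23, pan-myeloid markers in 22 of 23, cytokine genes in 18 of 22 with 2 rises, antigen presentation genes in 17 of 18, homeostatic markers in 17 of 21 with 1 rise, and myeloid transcription factors in 15 of 19 with 1 rise. Rises covered 24 of 25 pan-neuronal markers (log2 changes Dcx 2.58 and Stmn2 2.54), 20 of 25 neurogenic transcription factors (Neurod6 2.58, with 1 fall), 25 of 26 synaptic vesicle genes, 21 of 22 postsynaptic genes, 18 of 24 GABAergic genes, 15 of 19 channels, 20 of 20 cholesterol synthesis genes and 11 of 12 fibroblast and mural markers, where Acta2 went from 2.87 to 14.5 FPKM. Genes of p53 and apoptosis fell in 12 of 17 cases and rose in 1. These 16 lists had camera adjusted p between 1.41e-09 and 0.00576, and with an estimated correlation adjusted p between 0.252 and 0.316. Dnmt3a fell by 2.56 (SE 0.06, limma adjusted p = 3.56e-14), to 14.7 ± 0.178 FPKM. Among the 4 largest changes of each list, called members had an SE of 0.0401 to 0.178. In all, 3075 genes rose and 2867 fell. The median, mean and camera direction of a list differed in sign for the homeostatic, DNA methylation, glycolysis, endothelial and heat shock lists at day 2, glycolysis at day 7, Notch genes in the interaction, pan-myeloid and phagocytosis genes in control cells over time, and Notch and DNA methylation genes in ND1 cells over time. None of these was called.

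Neurons were compared with control microglia to give the reference difference between the cell types. Against control day 7, Tubb3 was higher by log2 7.13, Stmn3 by 7.30 and Scg2, a secretogranin gene of dense-core vesicles, by 7.28, and Gad1, which encodes a GABA-synthesising enzyme, stood at 166 ± 8.68 FPKM in neurons and 1.87 in control libraries (SD, n = 3 each). C1qa was lower by log2 -10.10, C1qb by -10.46 and Spi1, the gene of the myeloid transcription factor PU.1, by -7.68. All 25 pan-neuronal, 26 synaptic vesicle and 22 postsynaptic genes were higher, and 22 of 24 GABAergic and 19 of 20 cholesterol synthesis genes. Lower were 22 of 22 interferon-stimulated, 22 of 23 pan-myeloid, 22 of 23 phagocytosis and 17 of 23 cell cycle genes. Immediate early genes were higher in 9 of 16 cases and lower in 2 (camera adjusted p = 0.0317, and adjusted p = 0.368 with an estimated correlation), a call that ended with the 5 FPKM filter (0.150, the highest of a range from 0.0161 over the alternatives). The other 16 called lists had camera adjusted p between 5.33e-09 and 0.00630, and with an estimated correlation adjusted p between 0.202 and 0.243. For list members, the 4 largest called changes of each list had an SE of 0.0407 to 0.140. In all, 3824 genes were higher and 3436 lower.

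Against control day 2, the neuron difference covered 3982 higher and 3505 lower genes, led among list members by Sst (log2 10.40), Gap43 (8.13) and Stmn2 (7.88) and by Ccl5 (-11.62), Ctss (-10.14), a lysosomal protease gene, and Irf7 (-9.97). Gpnmb (-9.85) and Lgals3 (-9.68), lysosome-associated genes of phagocytes, were also lower. All 25 pan-neuronal, 26 synaptic vesicle, 22 postsynaptic and 19 channel genes were higher, and all 23 phagocytosis and 22 interferon-stimulated genes lower. The 17 called lists had camera adjusted p between 7.03e-09 and 0.0188, and with an estimated correlation adjusted p between 0.218 and 0.254. The call of fibroblast markers (7 of 12 higher) ended after quantile normalization (camera adjusted p = 0.0578) and under 2 other settings, with a range of 0.00812 to 0.0657 over the alternatives.

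The comparison of ND1 day 7 cells with neurons asked where the transduced cells still differed. Myeloid genes were higher in ND1 cells: Tyrobp, a myeloid signalling adaptor gene, stood at 299 ± 45.5 FPKM against 4.69 ± 0.790 in neurons (SD, n = 3 each; log2 change 5.72, SE 0.11), Lgals3 at 171 ± 25.7 against 2.27 FPKM, and Ctss at 221 ± 27.1 against 3.24 FPKM. Higher were 22 of 23 pan-myeloid markers (log2 changes Fcer1g 4.89 and Laptm5 4.82), 18 of 21 homeostatic markers (C1qa 5.24, C1qb 5.59 and C1qc 5.19), 20 of 22 interferon-stimulated genes (Ifi204 4.07 and Irf7 3.88), 16 of 23 phagocytosis genes (Clec7a 5.28), 16 of 22 cytokine genes (Ccl5 4.56 and Ccl4 3.39), 10 of 19 myeloid transcription factors (Spi1 3.54, with 1 lower) and 9 of 18 antigen presentation genes (B2m 3.73 and H2-K1 3.24, with 1 lower). The share of control day 7 levels named above, a median of 4.83% with the neuron mean subtracted, stands beside these groups. After its removal, 9 of 21 homeostatic markers were higher and 3 lower, and 9 of 23 pan-myeloid markers were higher and 4 lower. Interferon-stimulated genes were then higher in 4 of 22 cases and lower in 2, and phagocytosis genes higher in 9 of 23 and lower in 2. Many members of these lists are among the control-high, neuron-low genes whose median set the share. A split around it is thus largely built in. C1qa, C1qb, C1qc, Fcer1g, Irf7, Ccl4 and H2-K1 lay below the share removed, and values under 0 were set to 0. Their changes, from -0.79 for Ccl4 to -3.51 for H2-K1, set the neuron level against 0 and are not measured reversals. The antigen presentation list turned as well (camera adjusted p = 0.417). Neurogenic transcription factors were higher in 8 of 25 cases, among them Sox11 (82.2 ± 5.12 against 15.7 ± 2.82 FPKM), Insm1 (7.14 ± 0.280 against 1.11 FPKM) and Myt1l. Cell cycle genes were higher in 9 of 23 cases and lower in 1, with Mcm3, a replication helicase gene, at 1.71 and Rrm2 at 1.52, and Notch genes in 3 of 13, with Notch2 and Rbpj. Dnmt1, the maintenance DNA methyltransferase gene, was higher by 1.07 (SE 0.04, limma adjusted p = 5.68e-11), and Ezh2 by 1.95.

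Some neuronal and activity-regulated genes were lower in ND1 cells than in neurons, while most synaptic vesicle, postsynaptic and channel genes did not pass. Scg2 stood at 16.0 ± 0.165 FPKM against 354 ± 7.64 in neurons (SD, n = 3 each; log2 change -4.38, SE 0.07), Syp, the synaptophysin gene, at 81.5 ± 1.1 against 289 ± 15.3 FPKM, and Gad1 at 28 ± 1.40 against 166 ± 8.68 FPKM. Cartpt, a neuropeptide gene, stood at 0.371 against 41.7 ± 5.75 FPKM. The activity-regulated genes Fos (6.57 ± 0.206 against 78.2 ± 5.52 FPKM; log2 change -3.39, SE 0.05, limma adjusted p = 1.34e-14) and Npas4 (2.66 against 33.2 ± 2.82 FPKM) were lower too. Lower were 10 of 26 synaptic vesicle genes (log2 changes Sv2b -1.97 and Syn2 -1.64), 13 of 24 GABAergic and striatal genes (Penk -2.50), 8 of 16 immediate early genes (Nr4a1 -1.97), 5 of 19 channels (Scn1a -1.95), 4 of 22 postsynaptic genes (Camk2a -1.57 and Grin1 -1.52), 6 of 20 glycolysis genes with 2 higher (Pfkp -1.94 and Eno2 -1.88) and 4 of 17 heat shock genes with 2 higher (Atf4 -1.59 and Hspa5 -1.57). The 18 called lists, which include 2 of 14 progenitor markers higher (Msi1 1.25 and Nes 1.16), had camera adjusted p between 3.89e-11 and 0.0329, and with an estimated correlation adjusted p between 0.230 and 0.497. Pan-neuronal markers (4 of 25 higher, camera adjusted p = 0.640) and cholesterol synthesis genes (0 of 20, 0.515) were not called. Among list members, the 4 largest called changes of each list had an SE of 0.0357 to 0.189 and limma adjusted p up to 6.77e-07. In all, 991 genes were higher and 849 lower, and 509 higher once the control day 7 share was removed, a fall that the choice of the share in part builds in. Quantile normalization ended the calls of postsynaptic, glycolysis and progenitor genes (camera adjusted p 0.0593, 0.0633 and 0.0721, in ranges of 0.0131 to 0.0654, 0.0170 to 0.0633 and 0.00937 to 0.0721 over the alternatives), and the 5 FPKM filter those of Notch and heat shock genes (0.0636 and 0.0528, the highest of ranges from 0.00122 and 0.0171).

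Called genes were then counted across comparisons that share no library. Of the genes higher in neurons than in control day 2 cells, 2953 (74.2%) were also higher in ND1 than control cells at day 7, where 1024 would be shared by chance, and 2747 of the lower genes (78.4%) were shared, where 859 would be. Opposite calls numbered 3 and 23, and the log2 changes correlated across all tested genes at r = 0.894 and rho = 0.894. For the day 2 effect against the neuron to control day 7 difference, 1163 higher genes (30.4% of the neuron calls, 348 by chance) and 70 lower genes (2.04%, 21.2 by chance) were shared, with r = 0.670 and rho = 0.755. These 1163 and 70 became 769 and 120 after quantile normalization, 2218 and 139 with a pseudocount of 0.1 and 3781 and 3969 without the fold threshold. Removal of the ND1 day 7 share gave 28 and 19. That share was set on the day 2 rise of neuron-high genes, so a large fall from 1163 is built in and does not test the overlap. On the log2 distance from control day 2 to neurons, the median of the 3982 neuron-high genes lay at 24.4 to 28.8% in ND1 day 2 libraries, 88.0 to 88.6% in ND1 day 7 libraries and 2.44 to 4.04% in control day 7 libraries. For the 3505 neuron-low genes the values were 12.2 to 15.9%, 81.6 to 84.7% and 5.29 to 5.61%.

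**Figure D3:**
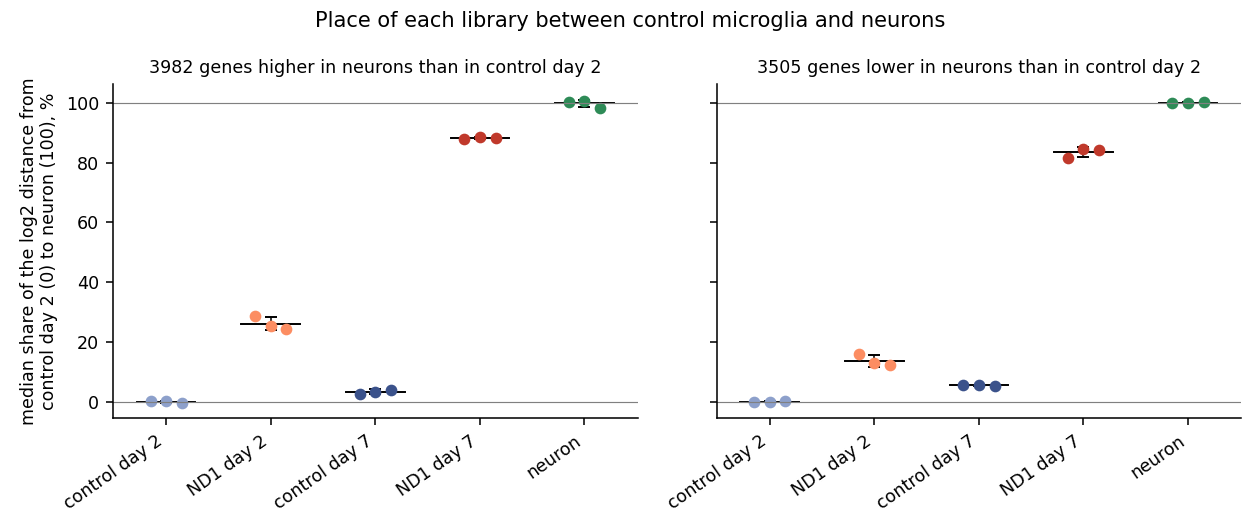
Median share (percent) of the log2 distance from control day 2 to neurons for neuron-high and neuron-low genes. Points are the 15 RNA libraries, with the mean and SD of each group (n = 3). ND1 day 7 libraries lie between 81.6 and 88.6%.

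**Figure D4:**
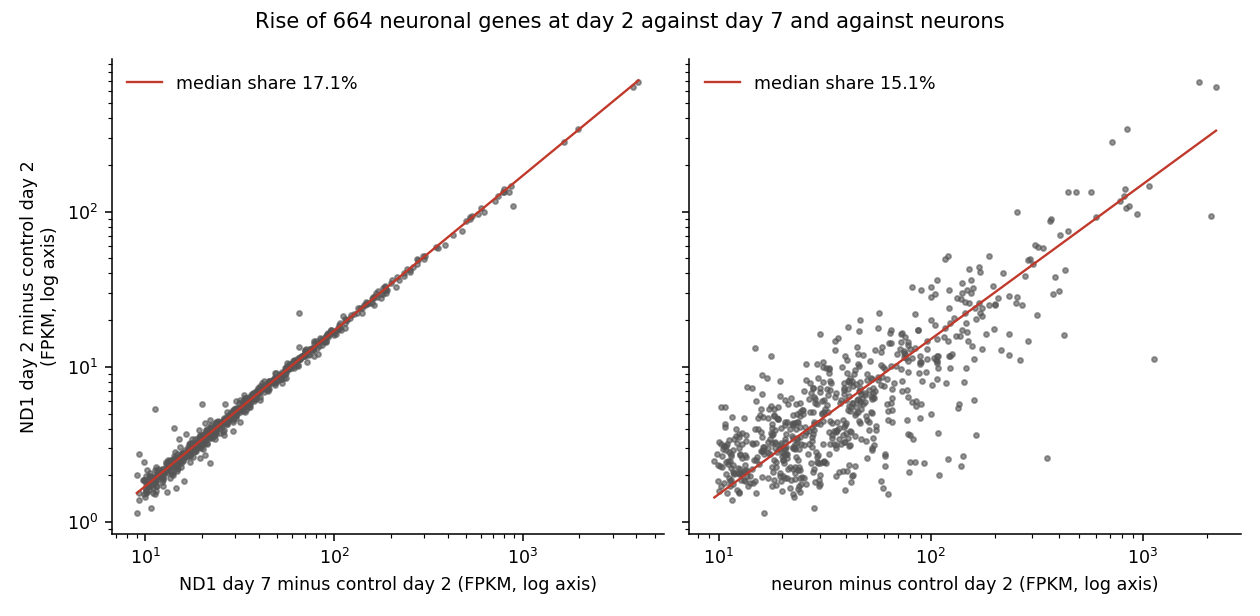
FPKM rise over control day 2 of 664 neuron-high genes in ND1 day 2 libraries (vertical, log axis) against the rise in ND1 day 7 (left) and the neuron level (right), each point a gene's group mean. Lines mark 17.1% and 15.1%, and the points scatter less around the left line (interquartile range 0.114 on the log2 scale) than around the right (1.05).

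Some transcripts were listed at 0 in whole groups. Fth1, which encodes ferritin heavy chain, was listed at 0 in all 6 day 2 microglia libraries, at 23848, 23058 and 22024 FPKM in control day 7 libraries, at 2796, 2184 and 2415 FPKM in ND1 day 7 libraries and at 1006, 1131 and 1262 FPKM in neurons. Mir1895, a microRNA gene, was listed at 0 in all 6 control libraries, at 450, 300.2 and 171 FPKM in ND1 day 2 libraries and at 1000, 474 and 932 FPKM in ND1 day 7 libraries. Mir6935 was listed at 231, 246 and 235 FPKM in ND1 day 2 libraries and at 0 elsewhere. Actr3, an actin-related protein gene chosen after its values were seen, was listed at 0 in all 6 control libraries and at 0, 0 and 407 FPKM in ND1 day 2 libraries. A listed 0 is therefore not read as absence of the transcript, and no change of Fth1 over time is given.

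The bisulfite libraries were compared to ask whether CpG methylation differed between control and ND1 cells. The mean level over 15108432 positions listed in both libraries was 70% in control and 70.3% in ND1, a difference of 0.280 points, with r = 0.938 across positions. The difference was 0.286 points on the autosomes. On chromosome X it was 0.0835 points, with r = 0.872. Pooled over positions, both ends of all genes averaged 27.8 and 27.9%, bodies without the ends 74.2 and 74.4%, and positions outside protein-coding genes 72.5 and 72.8%. Averaged by gene, CpG-richer ends stood at 31.3% in control and 31.5% in ND1, and whole-gene bodies at 63.2 and 63.4%. Of 19859 gene ends and 20308 gene bodies, 0 differed by 25 points or more, with r = 0.997 across genes for each. The largest falls at gene ends were those of Nxt2 (chromosome X, 142225770 to 142227270), from 72.9 to 52.1% over 11 positions, Hbb-bt, a beta-globin gene (chromosome 7, 103813423 to 103814923), from 87.8 to 68.9%, 4930513O06Rik, from 88.1 to 71.6%, Gm35586, from 59.7 to 43.2%, and Kctd12b, from 39.4 to 23.4%. Of these 5, all but Hbb-bt lie on chromosome X, where the 768 gene ends had an SD of 4.13 points and a median difference of -0.168, against 2.30 and 0.0754 points for 19091 on the autosomes. Listed positions of the Y chromosome numbered 6951 in control and 9041 in ND1, against 15809560 and 16265647 positions in all. A different sex makeup of the 2 libraries was not tested, so falls on chromosome X cannot be ascribed to ND1. The largest rises were those of Tfpi2 (chromosome 6, 3988478 to 3989978), from 68.7 to 92.3% over 5 positions, Vmn2r14, from 32.8 to 53.8%, Olfr506, from 29.8 to 48.3%, Cyp2c29, from 44.4 to 61.0%, and Gpr141, from 35 to 51.5%.

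Gene sets differed by under 2 points. Ends of genes that rose at day 7 differed by a median of 0.0869 points, at percentile 93.3 of random sets, and ends of genes that fell by 0.0762 points, at percentile 94.6. With ends of 500 bp on each side, and with ends from 2000 bp outside to 1000 bp inside, the genes that fell differed by 0.0680 and 0.120 points, at percentiles 99.4 and 99.8, above random ranges that reached 0.0627 and 0.106. The genes that rose lay at percentiles 77.1 and 55.9. The random range holds the central 95% of random sets, so some of 26 lists would lie outside it by chance alone. Of 26 lists, 2 lay outside the random range at gene ends: pan-myeloid markers, at -0.342 points where random sets began at -0.297, and postsynaptic genes, at 0.503 where they ended at 0.467. With ends of 500 bp on each side pan-myeloid markers lay at -0.483 points, below a range from -0.293, and with the longer ends at -0.0786, within it. Postsynaptic genes lay within the range under both, at 0.229 and 0.0657 points. Outside it only with the shorter ends were synaptic vesicle genes (-0.240), pan-neuronal markers (0.297), myeloid transcription factors (0.475) and DNA methylation genes (0.532), and only with the longer ends cytokine genes (0.504). Bodies of genes that fell differed by 0.247 points, above the random range of 0.163 to 0.209. Bodies of homeostatic microglia markers went from 55.8 to 57.3%, with a median difference of 1.28 points where random sets gave -0.142 to 0.469, and bodies of cytokine genes differed by -0.230 points, below a range from -0.106. Bodies of progenitor markers differed by 0.568 points, at the upper edge of theirs. Of 1702153 windows of 1 kb, 570 were lower and 709 higher in ND1 by at least 25 points, of which 551 and 685 lay among windows of 3 to 4 positions. With at least 10 positions, a minimum chosen after the data were seen, 2 windows were lower and 0 higher: chromosome 6, 39359001 to 39360000, at Slc37a3, a sugar phosphate transporter gene, from 90.6 to 43.4%, and chromosome X, 19349001 to 19350000, at 129420 bp from Tex13c3, from 89.7 to 44.2%. The limit named for chromosome X applies to the latter.

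**Figure D5:**
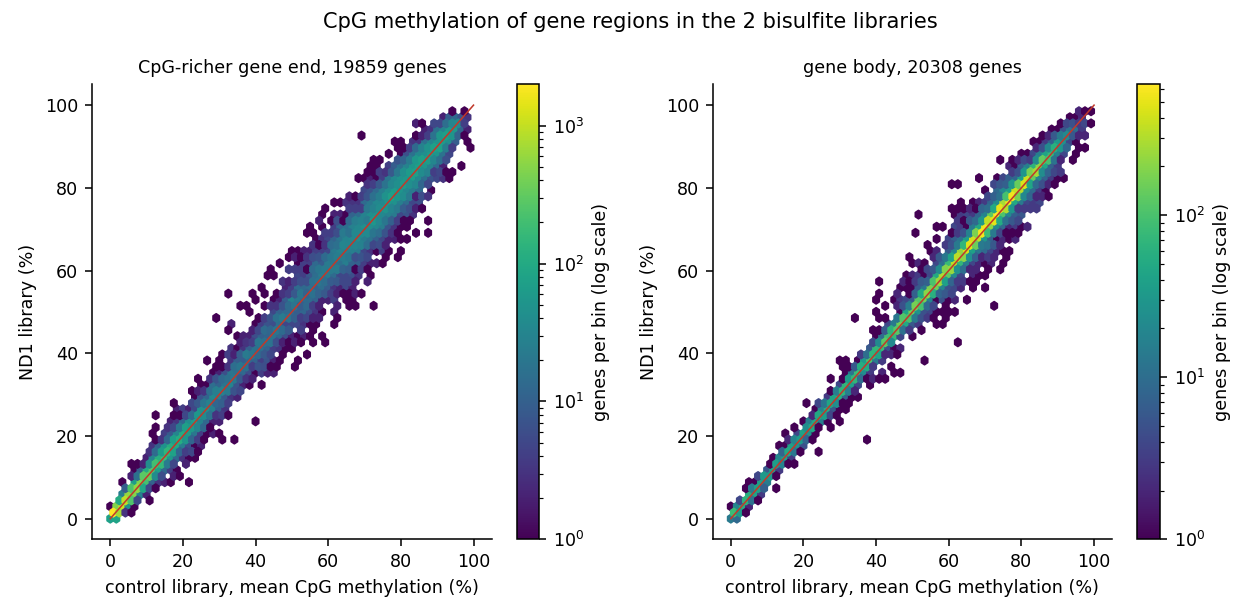
CpG methylation (percent) of the control library (horizontal) and the ND1 library (vertical) at 19859 gene ends and 20308 gene bodies, coloured by the number of genes on a log scale. The diagonal marks equal levels, and r is 0.997 across genes in both panels.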

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

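The tests of the 3 patterns weighed here, and the counts after removal of a share, were chosen after the result was seen, while the split counts were planned. The interaction term separated the ND1 effects of the 2 days for 5616 genes, of which 2790 had the higher and 2826 the lower effect at day 7. Cd33 rose at day 2 and fell at day 7, from 7.14 ± 0.287 FPKM in control to 2.46 ± 0.478 in ND1 libraries (SD, n = 3 each), with an interaction of -2.98 (SE 0.11, limma adjusted p = 1.35e-11). Olfml3 did likewise, with 14.8 ± 1.43 and 3.46 ± 0.471 FPKM at day 7 and an interaction of -3.23 (SE 0.11, limma adjusted p = 5.1e-12). The microRNA gene Mir7035 was listed at 0, 0 and 110 FPKM in control and 92.7, 49.9 and 46.5 FPKM in ND1 libraries at day 2, and at 92.9, 144 and 90.0 FPKM in control and 0 in all 3 ND1 libraries at day 7. Its interaction of -10.41 rests on values listed at 0.

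Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split alone, 1 of 10, gave as many called genes in each comparison of 3 against 3: 1321 for ND1 day 2 against control, where the highest other split gave 2, 6829 for day 7 (highest other 1), 1047 for control cells over time (1), 5942 for ND1 cells over time (2), 7487 and 7260 for neurons against control day 2 and day 7 (1 each) and 1840 for ND1 day 7 against neurons (2). For the interaction, 7 of 100 drawn splits of the 12 microglia libraries gave as many genes as the real 5616, with 6508 in the highest other, so chance is not excluded by this count. All 6 others came from the 21 splits that kept the 3 ND1 day 7 libraries on the same side of the contrast, which points to a structure of the samples, namely the distance of ND1 day 7 cells from the rest. The 78 splits that parted those libraries gave at most 3 genes.

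Neuronal genes stood at near 17.1% of their ND1 day 7 rise in ND1 day 2 libraries (library medians 19.4, 16.3 and 15.4%), with medians of 16.0 to 17.4% over the 6 neuronal lists. Different speeds of induction are argued against only between 2 lists: the median share of neurogenic transcription factors was 0.981 times that of synaptic vesicle genes, which mature neurons use, over the 9 and 21 members that passed the level filter. Over all 22 and 26 members called higher on either day the ratio was 0.972, and 0 of these fell between the days in ND1 cells. Single genes, chosen after their values were seen, lay apart: Vldlr at 48.1% and Cck at 33.9%, against Gnb4 at 11.4% and Eno2 at 10.9%. A ratio of list medians cannot exclude different speeds of such genes. Reads passing evenly between all libraries are argued against too, since control day 2 libraries held a median of 1.204% of the ND1 day 7 level (interquartile range 0.758 to 2.53%) over the 84 members of the neuronal lists with at least 10 FPKM at ND1 day 7, chosen without regard to their control level. RNA of the ND1 day 7 profile in each ND1 day 2 library may account for the pattern. A sample mixture or cross-talk from ND1 day 7 libraries would do this. The share varied between genes by 0.114 (interquartile range, log2), where replicate error gives 0.125. That error includes the shift of the share between libraries that genes have in common. It is thus too wide to show that the share is the same for every gene. All-or-none conversion of a part of the cells by day 2 stays open, because it and a mixture predict the same fall of myeloid genes. These stood at a median of 72.5% of control day 2 (interquartile range 65.1 to 81.1%). That is lower than replacement of 17.1% of the RNA alone would leave. Neither explanation by itself covers this further fall.

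Myeloid transcripts persisted in ND1 day 7 libraries. A fixed share of cells with the control day 7 profile is argued against as the whole cause. With the neuron mean subtracted from both groups, the share varied between 306 myeloid genes by 0.508 (interquartile range, log2), where replicate error gives 0.172. It ran from 0.970% for Cd5l and 2.25% for Lyz2 to 12.4% for S100a1, the last of which was chosen after its values were seen. Reads passing evenly between all libraries are argued against by neuron libraries at 0.163% of the control day 7 level over the homeostatic and pan-myeloid lists. Without that subtraction, ND1 day 7 libraries stood at 4.91% of the control day 7 level over the same 32 list genes. Transcripts left in changed cells and unconverted cells whose profile differs from control day 7 may each contribute. They cannot be told apart because no library holds single cells.

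The control and ND1 bisulfite libraries were near-identical in CpG methylation while expression changed widely at day 7. DNA mainly of another lineage in the ND1 library is argued against, for any lineage that is methylated at windows low in myeloid cells, a level not measured here. It would raise such windows by over 10 points, while 204 CpG-poor windows near myeloid list genes, at 17.2% in control, differed by 0.874 points (bootstrap 95% interval over windows 0.171 to 1.56). Those near neuronal list genes differed by 0.726 points (0.122 to 1.30) and all such windows by 0.506 points. The labels give no day, and each condition has 1 library, which keeps the other explanations open. DNA mainly of cells whose expression had not changed may explain the gene-body r of 0.997. Expression change without change of CpG methylation is also consistent with the 0.0869 points at ends of genes higher at day 7, and these cannot be told apart here.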

How the results depend on the processing

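The share removals, the minimum of 10 positions per window and the omission of genes listed at 0 or of small RNAs were chosen after the data were seen, and the other alternatives were planned. Summary counts kept within 1.5 times their value in 576 cases and moved further in 62, and the cause of these moves was not tested beyond what each setting changes by construction. Without the fold threshold, which admits small changes, higher and lower genes numbered 4300 and 4944 for ND1 at day 2, 6330 and 6015 at day 7, 6294 and 5327 for the interaction, 4598 and 4358 for control cells over time, 6591 and 5594 for ND1 cells over time, 6319 and 6102 for neurons against control day 2, 6439 and 5944 against day 7, and 5650 and 4565 for ND1 day 7 against neurons. Shared genes then numbered 5414 and 5152 for day 7 and neurons, 3781 and 3969 for day 2 and neurons, and 3838 and 4171 for both days. A pseudocount of 0.1, which enlarges changes of weak genes, gave 2367 and 157 at day 2, 1115 and 777 for control cells over time and 1737 higher genes for ND1 day 7 against neurons, with 2218 and 139 shared by day 2 and neurons and 2233 and 143 by both days. Quantile normalization gave 817 and 159 at day 2, with 769 and 120 shared by day 2 and neurons and 777 and 130 by both days. Removal of the ND1 day 7 share gave 98 and 41 at day 2, with 28 and 19 shared with neurons and 27 and 20 with day 7, and 3 of 27 lists called. Removal of the control day 7 share gave 509 higher genes and 10 called lists for ND1 day 7 against neurons. Each share was set on genes that these counts hold, so much of these falls is built in. With an estimated correlation 0 lists were called in 7 comparisons and 1, astrocyte markers, in control cells over time. The replicate block gave 1235 and 84 genes at day 2 and 3497 and 3332 at day 7, and 10 called lists in place of 11 for control cells over time. Methylation windows of 2 kb gave 253 lower and 343 higher, a difference of 40 points 9 and 9, and the minimum of 10 positions 2 and 0. Gene ends differed by 0.0523 points for genes higher at day 7 with ends of 500 bp on each side, and by 0.120 points for lower genes with ends from 2000 bp outside to 1000 bp inside.

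Leaving out each library in turn gave 1171 to 1280 higher and 74 to 91 lower genes for ND1 at day 2, 3500 to 3514 and 3306 to 3354 at day 7, 2756 to 2850 and 2799 to 2870 for the interaction, 517 to 553 and 503 to 508 for control cells over time, 3028 to 3117 and 2844 to 2917 for ND1 cells over time, 3964 to 3991 and 3496 to 3516 for neurons against control day 2, 3793 to 3836 and 3415 to 3452 against day 7, and 944 to 1004 and 835 to 889 for ND1 day 7 against neurons. All tested genes without a filter moved the median change by -0.102 for the interaction and -0.108 for ND1 cells over time. Named genes kept their call in 18261 cases, gained one in 268, lost one with the same sign in 82 and changed sign in 35, and lists in 4022, 26, 172 and 3 cases. Those that changed sign include genes that no longer passed, and all 3 lists.

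Each change of sign of a gene or list called before or after it in the RNA data came from the removal of a share. Such removal can overshoot where a gene's own share differs from the median. Values under 0 after removal were set to 0, so a change below 0 is not a measured reversal. After removal of the ND1 day 7 share, day 2 changes were -1.04 for Acat2, -0.24 for Acta2, -0.24 for Cacna2d1, -0.0749 for Cxcl1, -0.22 for Dlg2, -0.19 for Dlg4, -0.30 for Gabra2, -0.93 for Hmgcs1, -1.04 for Idi1, -0.52 for Ldhb, -0.94 for Mef2c, -0.68 for Meis2, -0.10 for Msi1, -0.0918 for Neurod6, -0.16 for Pfkm, -0.0939 for Pou3f2, -0.25 for Scn3b, -0.78 for Stmn2, -0.36 for Syt1 and -0.30 for Syt4. The lists of phagocytosis and cholesterol genes turned, with camera adjusted p 0.307 and 0.592. After removal of the control day 7 share, changes of ND1 day 7 against neurons were -1.91 for Bst2, -2.16 for C1qa, -1.98 for C1qb, -2.41 for C1qc, -1.05 for Ccl3, -0.79 for Ccl4, -1.92 for Fcer1g, -0.83 for H2-D1, -3.51 for H2-K1, -0.47 for Ifit3, -0.40 for Irf5, -1.03 for Irf7, -0.26 for Irf8, -0.32 for Lfng and -1.36 for Psmb8, and the antigen presentation list turned, with camera adjusted p 0.417. Gene ends of neural progenitor markers differed by 0.350 points with ends of 500 bp on each side, against -0.263 points, and the cause was not tested.

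Planned read minimums of 3 and 10, read-weighted levels and Fisher tests were not run, since the tables hold fractions without depth, so a methylation difference at a position or small window cannot be set against counting error. RNA depth limits weak genes: the lowest values step in units whose worth differs between libraries from 0.732 to 1.13.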

Other observations

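A small set of genes had opposite ND1 effects on the 2 days. Of 13 such genes, chosen after their values were seen, Abca9, a lipid transporter gene, went from 5.11 to 14.1 ± 1.36 FPKM at day 2 and stood at 18.2 ± 1.27 FPKM in control and 2.74 ± 0.269 FPKM in ND1 libraries at day 7 (SD, n = 3 each). Serpinb6b, a protease inhibitor gene, went from 7.38 ± 0.229 to 24.3 ± 1.86 FPKM at day 2 and stood at 18.3 ± 2.28 and 3.40 ± 0.268 FPKM at day 7. Arhgap18 had log2 changes of 1.08 and -2.38, Sesn1, a sestrin gene, 1.18 and -1.56, and Id3, which encodes an inhibitor of basic helix-loop-helix factors, 1.06 and -1.43. Others were Cd33, Cyp4f18, Gm5086, Hyal1, Mir7035, Olfml3 and Sh2d1b1. All 13 had an interaction adjusted p (limma) of at most 9.97e-05.

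After removal of the ND1 day 7 share from ND1 day 2 libraries, 73 of the 1237 higher and 27 of the 84 lower genes were called as before, of which 62 and 25 were not small RNA genes. They include Slco2b1, Cd33, Olfml3 and Tgfbr1, which are expressed by microglia, among the higher genes, and Gpr65, Fabp4, Thbs1, Ifitm6 and Cxcl10 among the lower.

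Positions of the mitochondrial genome, which no comparison used, were listed at a mean methylated fraction of 16.0% over 224 positions in the control library and 10.0% over 225 positions in the ND1 library. Unconverted cytosines would also be listed as methylated, and the bisulfite conversion of the libraries was not checked. These fractions are therefore not read as mitochondrial methylation or as a change of it. The Y chromosome had 6951 listed positions in control and 9041 in ND1. Some RNA values of 0 stand beside high values of the same group: Lipa, a lysosomal lipase gene, was listed at 477, 0 and 472 FPKM in control day 2 and 45.2, 35.7 and 0 FPKM in ND1 day 7 libraries. Such genes with a value over 20 FPKM in a replicate, small RNAs aside, numbered 23.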
